A study of Mus musculus with 7 samples.

How the data were processed

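The deposited tables hold raw UMI counts (unique molecular identifiers, which count molecules) per cell for genes and for annotated transcripts, and the authors' cell table gives each kept cell an identity. The labels list 7 samples in 4 groups, and the tables cover only the 2 libraries of the modified 5' protocol, so every comparison was made within these 2 libraries. The tables are marked as a subset, and which subset they are is not given in the sources used here. The same holds for the aligner, the counting tool and the use of strand. The labels name the genome build mm10 and the Seurat package. The authors' cell table of each library gives one library name for all of its cells, and the labels of the 2 samples name the same libraries, which set the replicate numbers.

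Transcripts were joined to genes through GENCODE M21 by transcript identifier. Of the 69994 transcripts in the tables, 69648 had a gene there and held 99.9% of the UMIs. Only barcodes in the authors' cell table were kept: 4814 of 6395 in replicate 1 and 1093 of 2124 in replicate 2, against a target of 4000 cells in the labels. Summed UMIs of every kept cell equalled the total in the authors' table. A further filter at 500 UMIs and under 15% mitochondrial UMIs removed no cell. Cell types were the authors' clusters from gene counts. Because these clusters were made from the same genes that were then tested, the gene tests between them are circular in part. Their p-values cannot show that the types exist, or how firmly they differ.

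UMIs were summed per library and cell type for the 6 types with at least 20 cells in each library, which gave 12 sums. Macrophages, with 62 and 7 cells, were left out of the tests. All sums were fitted together in edgeR 4.0.16 with TMM scaling, filterByExpr and quasi-likelihood tests, and p-values were adjusted by Benjamini-Hochberg at a false discovery rate of 0.05. The model held the cell type and the library. The SE of a log2 fold change is its size divided by the square root of its F statistic. The library was a block because each library gives every cell type, and without this replicate block the number of genes between alpha and beta cells went from 2525 to 1281. With 2 libraries and 5 residual degrees of freedom, p-values rest only on how far type differences varied between these libraries, pooled over 6 types. Nothing in the labels says that the 2 libraries came from separate animals.

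Isoform usage was tested with edgeR's diffSpliceDGE, each transcript against the others of its gene, with Simes p-values per gene and Benjamini-Hochberg adjustment. A gene can pass through a transcript other than the one whose share moves most, so the adjusted p of a transcript over all transcripts is given as its own. Transcripts needed 10 UMIs over the types compared and 5% of the gene's UMIs in either type. Effects are differences in a transcript's share of its gene's UMIs, in percentage points, as the mean over 2 libraries. The non-endocrine comparison set the mean of endothelial and stellate cells against the mean of the 4 endocrine types.

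The 14 gene lists were tested with limma 3.58.1, by camera with the preset correlation of 0.01, by camera with an estimated correlation, and by fry, with Benjamini-Hochberg adjustment over the 14 lists. Members that also belong to the 15 sets of cell type markers were left out. The genes named were, per comparison, the 12 with the largest rise and the 12 with the largest fall among genes past the threshold, above the median expression and changed in the same direction in each library, without markers, predicted genes and mitochondrial genes, and up to 4 members of each list by adjusted p. Isoforms were named by the same kind of rule, with at least 50 UMIs of the gene on each side of the comparison in each library, endothelial and stellate UMIs being added together, and 12 genes by difference in share. The tests, lists, naming rule and most alternative settings were fixed before the data were examined.

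Doublets were scored with Scrublet in scanpy 1.11.5 at an expected rate of 0.06. Its automatic threshold called 7 cells (0.145%) in replicate 1 and 16 cells (1.46%) in replicate 2, which is far under the expected rate, so an added alternative left out the 6% of cells with the highest scores in each library. Other alternatives used DESeq2 1.42.0, no TMM scaling, other filters, UMIs thinned to equal totals, the authors' clusters from transcripts, and only clusters led by their own type's markers. These own-marker clusters were a chosen list with no set cut-off, which left out beta cluster 5. A fold against a type with 0 UMIs is given against a floor of 3 UMIs over both libraries together, and for 1 to 3 UMIs a ratio with its 95% counting interval is given.

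Before use, the pipeline was run on simulated changes in 200 genes. For alpha against beta it recovered 37.3% of 2-fold changes and 90.9% of 4-fold changes, for delta 59.7% and 92.4%, and for PP 29.9% and 80.3%, while at most 0.135% of unchanged genes were called. For isoform usage diffSpliceDGE recovered 31% of 30-point shifts for alpha cells, 23% for delta cells and 36% for PP cells, with 0 false calls. limma on log ratios recovered 97%, 92% and 94%, with 15.8%, 25% and 8.82% of its calls false. Of 15-point shifts diffSpliceDGE recovered 8%, 0% and 6% for alpha, delta and PP cells, and limma 63%, 52% and 61%. Of 1.5-fold gene changes, 8.96%, 13.4% and 2.99% were recovered in these types. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.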

Results

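Islets of Langerhans from female C57BL/6 mice, aged 10 weeks in the long-read samples, were profiled by droplet single-cell RNA sequencing with Nanopore long reads, which can span a whole transcript. The labels describe 4 groups: 1 sample of the 3' assay read with short reads, and 2 samples each of the 3' assay, the 5' assay and a modified 5' assay read with long reads after removal of insulin cDNA by a Cas9-based panel. In the modified 5' assay, dNTP was added at 2 steps, one extension was lengthened from 45 min to 2 h and another from 1 min to 3 min. Tables were available for the 2 modified 5' libraries, replicates 1 and 2, and the comparison of protocols was not analysed here.

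The libraries held similar totals over very different numbers of cells. Replicate 1 had 4814 cells and 11012364 UMIs with a median of 2110 UMIs and 1069 genes per cell, and replicate 2 had 1093 cells and 12092393 UMIs with a median of 9949 UMIs and 3331 genes per cell. A median cell held 840 annotated transcripts in replicate 1 and 2658 in replicate 2. With every cell thinned to 1000 UMIs, which left out 464 cells of replicate 1 in the gene table and 679 in the transcript table, the medians were 617 and 602 genes and 552 and 525 transcripts. Per library, 21548 ± 39.6 genes and 56624 ± 279 transcripts were detected (mean ± SD, n = 2). Transcripts joined to a gene averaged 56351 per library over 20420.5 genes, or 2.76 ± 0.0126 transcripts per gene. In both libraries 57.6% of these genes (11761 of 20414 and 11768 of 20427) had at least 2 transcripts. The exact binomial 95% interval was 56.9 to 58.3% in each. It treats genes as random draws and covers neither counting error of UMIs nor spread between libraries. At an equal 30 UMIs per gene, the mean number of transcripts per gene in replicate 1 was 2.35 in alpha, 2.18 in beta, 2.30 in delta and 2.14 in PP cells, and in replicate 2 it was 2.08, 2.10, 2.08 and 1.98, so the order of the types differed between libraries.

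Beta cells, which secrete insulin, were the largest type, at 47.4% of replicate 1 (exact interval 46.0 to 48.9%) and 39.8% of replicate 2 (36.9 to 42.8%). Alpha cells, which secrete glucagon, made up 20.9 ± 1.35% of cells, the class named delta, whose hormone is somatostatin, 24.6 ± 6.40%, and PP cells, which secrete pancreatic polypeptide, 4.81 ± 1.50% (mean ± SD, n = 2). Cells named endothelial made up 2.65 ± 0.389%, of which 8.51% in replicate 1 and 61.5% in replicate 2 lay in a cluster with duct markers, stellate cells 2.46 ± 0.0135% and macrophages 0.964 ± 0.458%. The hormone transcripts followed the names: Gcg stood at 235142 ± 97587 CPM (UMIs scaled to a common library total) in alpha cells against 1800 ± 976 in beta cells, Sst at 80956 ± 18018 CPM in the delta class against 824 ± 222 in beta cells, and Ppy at 162421 ± 44742 CPM in PP cells against 2033 ± 1272 in beta cells. Ins1 and Ins2, targets of the removal panel, stood at 2859 ± 688 and 7005 ± 1302 CPM in beta cells, below Iapp, the amylin gene, at 108792 ± 13793 CPM. Transcripts of Hhex, a delta-cell transcription factor, stood at 220.8 ± 49.1 CPM in the delta class and 2.54 ± 0.0460 in beta cells. Endothelial Plvap reached 3356 ± 3165 CPM, and pericyte-type Rgs5 reached 5078 ± 1195 CPM in stellate cells.

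**Figure D1:**
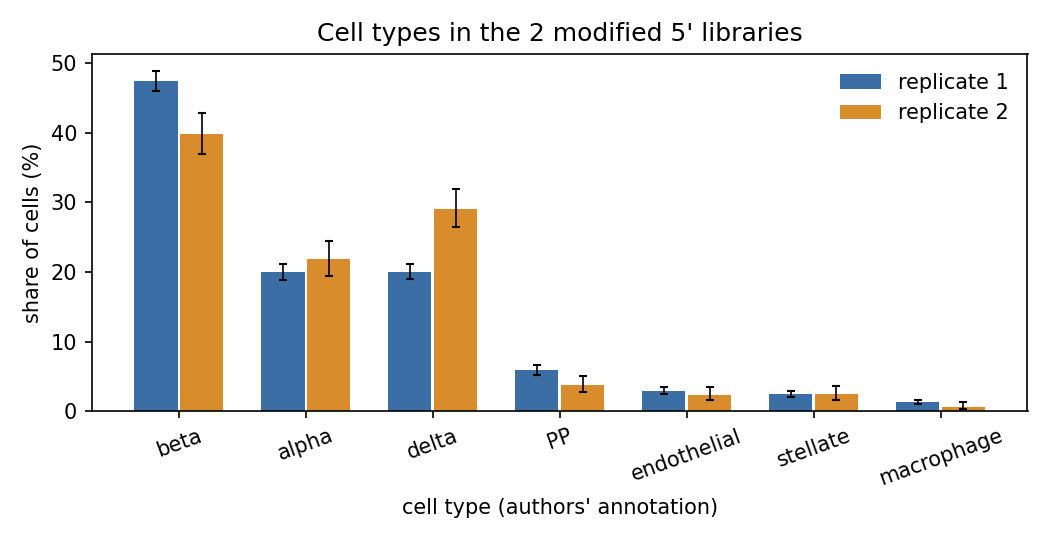
Share of cells (%) of each cell type in replicates 1 and 2 of the modified 5' group. Bars are shares per library and error bars are exact 95% binomial intervals, which cover counting error only. Beta cells form the largest class in both libraries.

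The delta class held cells of several kinds. Its cluster led by delta markers contained 435 cells in replicate 1 and 157 in replicate 2, which is 45.1 and 49.4% of the class. A second cluster of 295 and 27 cells had 0.440 and 0.657 times the library's median UMIs. Clusters with Sst beside Iapp and Ins2 (163 and 76 cells) and with Sst beside Gcg (45 and 41 cells) had 1.56 to 1.90 times the median UMIs. A cluster of 20 and 10 cells carried Mki67, a proliferation marker, at 448 and 289 CPM. The last, of 7 and 7 cells, carried Vip, a neuropeptide, at 8369 and 5051 CPM and Prph, a neuronal intermediate filament, at 3707 and 3639 CPM, with Sst at 0 and 39.3 CPM. Naming cells by their most abundant hormone changed the name of 31.5 and 23.0% of delta-class cells.

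Alpha cells differed from beta cells in 2525 of 13265 genes tested (edgeR, adjusted p < 0.05), with 1211 higher and 1314 lower in alpha cells. The largest rises included Edn3, which encodes endothelin 3 (chromosome 2, 174760619 to 174784042, log2 fold change 7.86 ± 0.39 SE, adjusted p = 1.6e-14), at 171 ± 8.22 CPM in alpha and 0.725 ± 0.784 in beta cells. Genes for the metalloprotease Pappa2, which acts on proteins that bind insulin-like growth factors, and for the amino acid transporter Slc38a5 rose by 6.02 ± 0.30 and 6.06 ± 0.29 log2 units, and Pdk4, a kinase that inhibits pyruvate dehydrogenase, rose by 6.96 ± 0.38. The largest falls included Msln, which encodes mesothelin (-5.88 ± 0.44), the cytochrome oxidase subunit gene Cox6a2 (-5.12 ± 0.32) and the cation channel gene Trpm5 (-4.89 ± 0.38, from 568 ± 44.6 CPM in beta to 18.9 ± 18.3 in alpha cells).

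Among the other largest rises, Sgce had a log2 fold change of 6.37, Tgm3 6.34, Oat 6.27 and Basp1 6.13. Higd1a, a mitochondrial protein induced by low oxygen, had 650 UMIs in alpha and 3 in beta cells, a ratio of 507 (counting interval 173 to 2467). Id1, a repressor of basic helix-loop-helix factors, had 105 UMIs against 1, a ratio of 246 (43.2 to 9805). Atf3, a stress-induced transcription factor, rose by 6.11 ± 0.59 with 123 and 992 UMIs in the alpha cells of replicates 1 and 2, a call that ended without the library block. Falls also took in Th, which encodes the rate-limiting enzyme of catecholamine synthesis, at -4.77, the muscarinic receptor gene Chrm3 at -4.75, Car15 at -5.18, Fam151a at -4.99, Tmem215 at -4.85, Nupr1 at -4.78 and Fkbp1b at -4.74. Mef2c had 0 UMIs in alpha and 30 in beta cells, at least 4.27-fold lower, and Prss23 had 1 against 107, a ratio of 45.7 (8.03 to 1821).

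Values given for single list members are log2 fold changes against beta cells. By list, genes of ER protein folding stood lower in alpha cells: 12 of 24 fell and none rose, or 13 adjusted over the list alone, with a median log2 fold change of -0.69 (camera adjusted p = 1.2e-07, and adjusted p = 0.171 with an estimated correlation). Ero1lb, an oxidase for disulfide bonds, fell by 3.11 ± 0.28 log2 units, from 1580 ± 60.4 to 186 ± 70.7 CPM, with Sdf2l1 at -1.90, Creld2 at -1.29 and Dnajb11 at -1.28. Hormone and neurotransmitter receptors went mostly down, with 13 of 19 lower and 3 higher (the same counts adjusted over the list alone, median -2.02, camera adjusted p = 3.3e-05, adjusted p = 0.0513 with an estimated correlation). The prolactin receptor gene Prlr fell by 4.10 ± 0.32 and the adrenergic receptor gene Adra2a by 3.98, while Gria2, a glutamate receptor subunit, rose by 4.22 ± 0.24 and the fatty acid receptor gene Ffar4 by 3.08 ± 0.25. Immediate early and dissociation stress genes rose in 12 of 18, also adjusted over the list alone, with a median of 1.62 (camera adjusted p = 1.0e-06, adjusted p = 0.248 with an estimated correlation), among them Zfp36 at 3.51, Ier2 at 2.73 and Jun at 2.67. Cytosolic ribosomal protein genes rose in 12 of 30, or 20 adjusted over the list alone, with a median of 0.73 (camera adjusted p = 3.6e-08, adjusted p = 0.328 with an estimated correlation) that was 0.31 without TMM scaling, or 0.70 relative to all genes there (main 0.72). Rpl27a rose by 1.17 and Rpl13 by 1.06. Ribosomal calls numbered 17 by DESeq2, 25 with only own-marker clusters, 3 without TMM scaling and 2 without the library block, where 5 immediate early genes rose, 5 ER folding genes fell, and 3 receptor genes rose and 11 fell.

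Splicing regulators rose in 11 of 40 and fell in 1, the same adjusted over the list alone (camera adjusted p = 0.00062, adjusted p = 0.0513 with an estimated correlation), and their median of 0.35 turned to -0.07 without TMM scaling, or 0.33 relative to all genes there. Mbnl2 at 1.12, Tra2a at 1.07 and Srsf5 at 1.00 were among the rises. The counts were 6 higher and 5 lower without TMM scaling, and 6 and 0 without the library block. Nuclear genes of oxidative phosphorylation fell in 5 of 18, or 7 adjusted over the list alone (median -0.38, camera adjusted p = 0.0047, adjusted p = 0.519 with an estimated correlation). Cox5a stood at -1.18 and Atp5g1 at -1.15, and without the library block 0 calls of this list were left. UMIs of genes on the mitochondrial genome took 0.857 and 1.64% in alpha, 1.02 and 1.83% in delta-class and 0.625 and 1.27% in PP cells against 1.52 and 3.66% in beta cells, and whether these shares and the list share a cause such as cell quality was not tested. Glucose uptake and glycolysis genes fell in 5 of 20 and rose in 1, or 7 and 1 adjusted over the list alone (median -0.35, camera adjusted p = 0.041, adjusted p = 0.248 with an estimated correlation). The glucose transporter gene Slc2a2 fell by 4.37 ± 0.40, from 801 ± 225 to 38.4 ± 32.0 CPM, G6pc2, the islet glucose-6-phosphatase, by 4.43, and Pcx, pyruvate carboxylase, by 2.74.

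The remaining lists did not pass camera in alpha cells. Islet transcription factors had 4 higher and 4 lower of 25 (the same adjusted over the list alone, 3 and 10 without TMM scaling, adjusted p = 0.996), with a median of -0.07, a mean of 0.33 and an upward test direction: Etv1, an ETS factor, rose by 5.52 ± 0.29, while Pdx1, which beta cells need for insulin transcription, fell by 3.69 ± 0.29 and Insm1 by 1.53. Ion channel genes had 4 higher and 5 lower of 19, also adjusted over the list alone (adjusted p = 0.786, camera downward and fry upward). The background potassium channel gene Kcnk3 stood at 5.09 ± 0.28 and the sodium channel gene Scn3a at 2.41. Prohormone and granule genes had 4 higher and 2 lower of 16 (5 and 2 adjusted over the list alone, adjusted p = 0.655), and without TMM scaling 3 higher and 7 lower, as the median went from 0.22 to -0.20. The convertase gene Pcsk1 stood at -3.74 and Scg2 at -1.79. Exocytosis genes had 1 higher and 6 lower of 21, also adjusted over the list alone (adjusted p = 0.127). The granule protein gene Sytl4 stood at -3.95 and Rab3b at -1.62. Diabetes genes had 2 higher and 4 lower of 23, also adjusted over the list alone (adjusted p = 0.179), with Wfs1, the Wolfram syndrome gene, at -2.29 and Glis3 at -1.54, a call that DESeq2 did not make. Genes with well-known isoforms had 8 higher and 7 lower of 49 (9 and 8 adjusted over the list alone, adjusted p = 0.655, median 0.06, or 0.08 with a gene at 0 UMIs set at its bound, and mean -0.05). Ppp1r1a stood at -4.14 and Gnas at 2.25. Long noncoding RNAs had 1 higher, Snhg11 at 1.75, and 1 lower, Neat1 at -2.19, of 9, also adjusted over the list alone (adjusted p = 0.655). Alpha and PP sums had TMM factors of 0.798 to 0.817 against 1.08 in beta sums, and without TMM the median of all genes moved from 0.02 to -0.39 in alpha cells and the calls to 708 higher and 3335 lower. By list, the lower genes then numbered 21 for ER folding, 13 for receptors, 13 for oxidative phosphorylation, 9 for glycolysis, 10 for transcription factors, 9 for ion channels, 9 for exocytosis, 10 for diabetes genes, 13 for genes with well-known isoforms and 2 for long noncoding RNAs. Ion channels had 3 higher and 1 lower without the library block and 2 and 1 by DESeq2. With only own-marker clusters prohormone genes had 8 higher and 4 lower, glycolysis genes 1 and 8, ER folding genes 0 and 15 and genes with well-known isoforms 11 and 10.

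The delta class differed from beta cells in 1829 genes, with 1165 higher and 664 lower in the class (edgeR). By DESeq2 the class had 840 higher and 355 lower, and without the library block it had 666 and 196. Its largest rises included Prph (chromosome 15, 99055174 to 99058978), up by 8.64 ± 0.39 log2 units (adjusted p = 1.1e-14), Sncg, a synuclein, by 8.30 ± 0.47, the neuropeptide gene Vip by 7.66 ± 0.45 and Stmn2, a microtubule regulator of neurons, by 7.51 ± 0.56. Of the class's UMIs of these 4 genes, 99.2 to 100% lay in the cluster of 7 and 7 cells. Cd24a, which encodes a surface glycoprotein, rose by 7.09 ± 0.34 and Gap43, a growth-cone protein, by 7.84 ± 0.47, and 11.9 to 39.0% of their UMIs lay in that cluster. The largest falls were Emid1 at -3.25 ± 0.35, Nupr1 at -2.90, Gstm2 at -2.69 and Cox6a2 at -2.40 ± 0.23. With only clusters led by their own markers, which left out 54.9 and 50.6% of the delta class and 13.8 and 12.9% of beta cells, these stood at -4.47, -5.55, -4.51 and -5.38. The beta cells left out in replicate 1, cluster 5, also had beta markers highest, with Iapp at 108714 CPM (100215 in kept cluster 4). Their Ins2 stood at 5377, Ppy at 6924 and Sst at 1745 CPM.

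Ldha, lactate dehydrogenase A, rose by 7.003 ± 0.40 in the class, with 91.96 and 94.1% of its UMIs in the same small cluster. Few UMIs in beta cells stood behind Lgals1 (908 against 2, a ratio of 677, interval 187 to 5600), Fxyd7 (1070 against 3, 532, 182 to 2584), Ptn (244 against 1, 364, 64.7 to 14432), Gng3 (540 against 3, 268, 91.4 to 1306) and Anxa2 (384 against 3, 191, 64.8 to 930). Further falls were T2 at -2.55, Tmigd3 at -2.41, Trpm5 at -2.39, Mt2 at -2.37, Th at -2.30, Tmem215 at -2.29, Adh1 at -2.28 and Cib3 at -2.23. With only own-marker clusters the values were Ldha 3.68, Anxa2 1.54 and Lgals1 2.53, the last 2 no longer calls, and T2 -4.40, Tmigd3 -5.29, Trpm5 -4.50, Tmem215 -3.91, Adh1 -3.90 and Cib3 -3.75. Under the authors' clusters from transcripts, which name 7 and 6 of the 7 and 7 cells beta, 12 named genes of this comparison changed sign. Among them were Prph, Sncg, Vip, Stmn2, Rtn1 and Snhg11, the last not past the threshold.

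In the delta class ER folding genes fell in 8 of 24 and rose in 0, or 12 lower adjusted over the list alone (median -0.59, camera adjusted p = 6.6e-06, adjusted p = 0.272 with an estimated correlation). Ero1lb stood at -1.57, or -3.12 with only own-marker clusters, Sdf2l1 at -1.03 and Hyou1 at -0.81. Immediate early genes rose in 11 of 18, or 12 adjusted over the list alone (median 1.01, camera adjusted p = 1.0e-05, adjusted p = 0.358 with an estimated correlation). Among them were Atf3 at 3.86, Jun at 2.06 and Ier2 at 2.00, and all 11 calls ended without the library block. Receptor genes had 5 higher and 11 lower of 19, also adjusted over the list alone (median -0.73, mean -0.01, camera adjusted p = 0.044, adjusted p = 0.272 with an estimated correlation). Ffar4 stood at 3.07, Gria2 at 2.77, the fatty acid receptor gene Ffar1 at -1.81 and Prlr at -1.61, with Ffar4 at 5.03, Ffar1 at -3.21 and Prlr at -3.07 when only own-marker clusters were kept. Splicing regulators rose in 5 of 40 and fell in 0, or 6 higher adjusted over the list alone (median 0.24, camera adjusted p = 0.016, adjusted p = 0.253 with an estimated correlation). Snrpn stood at 0.93 and Ptbp2, a neuronal splicing repressor, at 0.73. With only own-marker clusters Ptbp2 stood at 0.61 and was no longer a call. Oxidative phosphorylation genes fell in 3 of 18, also adjusted over the list alone (median -0.27, camera adjusted p = 0.024, adjusted p = 0.614 with an estimated correlation). Ndufb9 stood at -0.73, or -0.45 in replicate 2 alone. Without the library block 1 ER folding gene, 3 splicing regulators and 0 oxidative phosphorylation genes were left, with receptors at 4 higher and 5 lower, and the calls for Sdf2l1, Hyou1, Snrpn and Ndufb9 ended. DESeq2 did not make the Ptbp2 call, and it had 6 ER folding genes and 2 oxidative phosphorylation genes lower, 7 immediate early genes higher, and receptors at 4 higher and 6 lower.

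Of the other lists in the delta class, none passed camera. Without the library block, prohormone genes had 0 higher and 1 lower, exocytosis genes 2 and 1, genes with well-known isoforms 4 and 0, and diabetes genes 0 and 1. Transcription factors had 5 higher and 4 lower of 25 (6 and 4 adjusted over the list alone, adjusted p = 0.279). Etv1 stood at 4.28 ± 0.28 and Pdx1 at -0.68, and all 4 lower calls ended by DESeq2 (5 higher, 0 lower) and without the library block (3 and 0). Ion channels had 4 higher and 2 lower of 19 (6 and 3 adjusted over the list alone, adjusted p = 0.315). Kcnk3 stood at 2.87 and Scn3a at 2.59. Glycolysis genes had 2 higher and 4 lower of 20, also adjusted over the list alone (adjusted p = 0.572, median -0.04 and mean 0.29). Slc2a2 stood at -2.05, G6pc2 at -2.02 and Pcx at -1.47, and with only own-marker clusters at -3.74, -4.05 and -2.58. Prohormone genes had 3 higher and 2 lower of 16, also adjusted over the list alone (adjusted p = 0.683). The zinc transporter gene Slc30a8 stood at -1.55, from 1158 ± 67.6 to 395 ± 64.4 CPM, or -3.43 with only own-marker clusters. Exocytosis genes had 3 higher and 4 lower of 21 (3 and 5 adjusted over the list alone, adjusted p = 0.609, median -0.01 and mean 0.21). Sytl4 stood at -1.79, or -3.38 with only own-marker clusters, and Rab3b, whose call ended without the library block, at 1.21. Genes with well-known isoforms had 8 higher and 3 lower of 49, also adjusted over the list alone (adjusted p = 0.419). Rtn1 stood at 3.84, or 1.44 with only own-marker clusters, App at 1.45 and Tpm1 at 1.34. Diabetes genes had 0 higher and 3 lower of 23, also adjusted over the list alone (adjusted p = 0.622, median 0.09 and mean -0.02), and ribosomal protein genes had 0 calls of 30 by edgeR, by DESeq2 and at an unadjusted p under 0.05 (0 adjusted over the list alone, adjusted p = 0.419). Long noncoding RNAs had 1 higher, Snhg11 at 2.55 (1.11 with only own-marker clusters), and 0 lower of 9, also adjusted over the list alone (adjusted p = 0.301). With only own-marker clusters the lists of this comparison had, higher and lower, ER folding 0 and 16, immediate early 15 and 0, receptors 3 and 11, splicing regulators 10 and 1, oxidative phosphorylation 0 and 5, transcription factors 9 and 5, ion channels 8 and 3, glycolysis 1 and 5, prohormone 3 and 4, exocytosis 3 and 6, well-known isoforms 12 and 8, diabetes 3 and 4, ribosomal 1 and 0 and long noncoding RNAs 2 and 1.

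PP cells differed from beta cells in 2297 genes, with 1179 higher and 1118 lower in PP cells (edgeR). Rcn3, which encodes a calcium-binding protein of the ER (chromosome 7, 45082913 to 45092221), rose by 7.16 ± 0.37 log2 units (adjusted p = 7.0e-14), to 460 ± 28.7 CPM from 3.24 ± 1.45 in beta cells. Edn3 at 6.50 ± 0.47, Sgce at 6.35, S100a16 at 5.87, Oat at 5.74 and the acetylcholinesterase gene Ache at 5.72 ± 0.41 were also among the largest rises. The largest falls included Cox6a2 at -5.50 ± 0.41, G6pc2 at -5.03 ± 0.45 (66.0 ± 38.1 against 2090 ± 581 CPM), Prss53 at -5.27 and Slc2a2 at -4.72. Emid1 had 0 UMIs in PP and 461 in beta cells, at least 23.9-fold lower, and Gad1, which makes the transmitter GABA, had 2 against 1128, a ratio of 87.6 (24.2 to 724).

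Other genes in PP cells rested on few UMIs in one type: Id1 (38 against 1, a ratio of 245, interval 41.4 to 9920), Higd1a (56 against 3, 120, 39.1 to 601) and Ccn1 (15 against 1, 96.6, 14.9 to 4068) stood higher, and Msln (2 against 1201, 93.2, 25.7 to 771) and Cib3 (3 against 718, 37.2, 12.7 to 181) lower. Atf3 rose by 6.35 ± 0.60, or 3.79 without replicate 2, a call that ended without the library block. Tmem215 at -5.07, Papss2 at -4.88, Itpkb at -4.85 and Car10 at -4.60 were further falls. The Ache call ended under the authors' clusters from transcripts, and without TMM the median of all genes moved from -0.03 to -0.42 and the calls to 656 higher and 2746 lower. By list, the lower genes then numbered 12 for receptors, 10 for diabetes genes, 13 for ER folding, 9 for exocytosis, 8 for glycolysis, 11 for transcription factors, 8 for ion channels, 5 for prohormone genes, 17 for genes with well-known isoforms, 6 for oxidative phosphorylation and 5 for long noncoding RNAs.

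Immediate early genes rose in 13 of 18 in PP cells, or 15 adjusted over the list alone (median 2.03, camera adjusted p = 1.8e-09, adjusted p = 0.152 with an estimated correlation). Zfp36 stood at 3.70, Ier2 at 3.603 and Jun at 3.22. Ribosomal protein genes rose in 5 of 30, or 6 adjusted over the list alone (median 0.52, camera adjusted p = 3.3e-06, adjusted p = 0.487 with an estimated correlation), with a median of 0.11 without TMM scaling, or 0.53 relative to all genes there (main 0.55), and Rpl27a at 1.12. Ribosomal calls numbered 9 by DESeq2, 10 with only own-marker clusters, 1 without TMM scaling and 1 without the library block. Receptor genes had 3 higher and 11 lower of 19, also adjusted over the list alone (median -1.63, camera adjusted p = 0.0010, adjusted p = 0.135 with an estimated correlation): Glp1r, the receptor for the incretin GLP-1, fell by 4.45 ± 0.42, from 556 ± 17.99 to 26.9 ± 13.3 CPM, and Prlr by 3.94, while Ffar4 rose by 3.44 and Gria2 by 3.40. Diabetes genes fell in 6 of 23 and rose in 0, also adjusted over the list alone (median -0.48, camera adjusted p = 0.0057, adjusted p = 0.135 with an estimated correlation). Slc30a8 stood at -2.72, Pdx1 at -2.58 and Wfs1 at -1.75. With a gene at 0 UMIs set at its bound, the median was -0.47. ER folding genes fell in 4 of 24 and rose in 0, also adjusted over the list alone (median -0.32, camera adjusted p = 0.015, adjusted p = 0.487 with an estimated correlation). Ero1lb stood at -3.69 and Hyou1 at -1.66. Splicing regulators had 10 higher and 2 lower of 40, or 11 and 3 adjusted over the list alone (camera adjusted p = 0.023, adjusted p = 0.135 with an estimated correlation), and their median of 0.21 turned to -0.20 without TMM scaling, or 0.22 relative to all genes there, with Hnrnpa1 at 1.00 a call that ended there. The counts were 1 higher and 5 lower without TMM scaling, and 1 and 0 without the library block, where 6 immediate early genes rose, and 3 diabetes and 2 ER folding genes fell.

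The other lists did not pass camera in PP cells. Without the library block, transcription factors had 3 higher and 2 lower, ion channels 2 and 2, prohormone genes 0 and 2, exocytosis genes 1 and 3 and genes with well-known isoforms 3 and 4. With only own-marker clusters ER folding genes had 1 higher and 7 lower, genes with well-known isoforms 12 and 15 and splicing regulators 13 and 4. Exocytosis genes had 1 higher and 6 lower of 21, also adjusted over the list alone (adjusted p = 0.0782). Sytl4 stood at -4.52 and the vesicle GTPase gene Rab27a at -1.25. Glycolysis genes had 1 higher and 5 lower of 20 (2 and 5 adjusted over the list alone, adjusted p = 0.270). Pcx stood at -3.32 and Gpd2 at -2.37. Transcription factors had 4 higher and 6 lower of 25, also adjusted over the list alone (adjusted p = 0.796, median -0.43, or -0.28 with a gene at 0 UMIs set at its bound, mean 0.14, camera downward and fry upward). Etv1 stood at 5.31 ± 0.29, Insm1 at -1.93 and Rfx6 at -1.57. Ion channels had 5 higher and 5 lower of 19 (5 and 6 adjusted over the list alone, adjusted p = 0.523). Kcnk3 stood at 4.07, Scn3a at 2.51 and Trpm5 at -4.57. Prohormone genes had 4 higher and 3 lower of 16, also adjusted over the list alone (adjusted p = 0.954, median 0.04, mean -0.19, camera upward and fry downward). Pcsk1 stood at -2.45 and Scg5 at 1.29. Genes with well-known isoforms had 6 higher and 11 lower of 49 (9 and 14 adjusted over the list alone, adjusted p = 0.954, median 0.06, or 0.17 with 2 genes at 0 UMIs set at their bounds, mean -0.23 and a downward test). Ppp1r1a stood at -4.06 and Rtn1 at 1.90. Rtn1 reversed under the authors' clusters from transcripts, and the calls for Rfx6 and Scg5 ended without the library block. Oxidative phosphorylation genes had 0 higher and 2 lower of 18, also adjusted over the list alone (adjusted p = 0.396) and 0 lower without the library block, and long noncoding RNAs 0 calls of 9 by edgeR and by DESeq2 (5 lower without TMM scaling), 4 at an unadjusted p under 0.05, or 1 higher and 3 lower adjusted over the list alone (adjusted p = 0.523).

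Long reads allowed the mix of transcripts of a gene to be compared between types. Alpha cells used a different mix from beta cells in 55 of 5541 genes tested (edgeR diffSpliceDGE). In this and the next paragraphs on isoforms an adjusted p is that of the gene, over all of its transcripts, unless it is called the transcript's own. At Gnas, which encodes the stimulatory G protein alpha subunit (chromosome 2, 174284320 to 174346744), the transcript Gnas-221 took 21.7 and 31.0% of UMIs in alpha cells of replicates 1 and 2 (1143 and 1413 UMIs of the gene) against 2.25 and 3.41% in beta cells (1247 and 615 UMIs), a difference of 23.5 ± 5.75 points (SD, n = 2, own adjusted p = 3.9e-19, gene adjusted p = 1.8e-28). Gnas-221 is annotated without a coding sequence, and Gnas-208, a full coding transcript, went from 34.5 and 38.2% in beta to 16.4 and 10.3% in alpha cells.

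Alpha cells had less of Sumo3-202, a transcript of a small ubiquitin-like modifier, at 6.86 and 6.03% against 33.5 and 27.9% (-24.3 ± 3.36 points, own adjusted p = 0.00017), while Sumo3-201, at 91.2 and 91.0% against 63.2 and 66.7%, did not pass its own test (adjusted p = 0.962). Distal first exons were used more at the ribonuclease genes Ang (Ang-202, 31.3 ± 4.46 points, adjusted p = 7.9e-09) and Rnase4 (Rnase4-201, 20.2 ± 2.82 points, adjusted p = 4.8e-08), which overlap on chromosome 14, so reads may be shared between them. Clta-203, a clathrin light chain transcript with a 36-base coding exon (chromosome 4, 44031400 to 44031435), stood at 16.8 and 13.5% against 5.97 and 5.57% (adjusted p = 0.00060), and Dusp1-203, the transcript with a retained intron of a stress-induced phosphatase gene, at 15.6 and 2.04% against 41.8 and 25.7% (own adjusted p = 2.9e-07), both calls that ended without the library block. Calls at Snhg11 (adjusted p = 0.044), Plgrkt (0.011), Ddx50 (0.042), Mat2a (0.0033) and Mast4 (0.015) each ended under at least 1 alternative, and Fosb (0.024) rested on replicate 2, where Fosb-201 took 35.8% in alpha cells against 2.55% in replicate 1.

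The delta class used a different mix of transcripts from beta cells in 49 of 6006 genes (edgeR diffSpliceDGE). Of the 49, 17 were also called with only own-marker clusters and 23 under the authors' clusters from transcripts. Gnas again led: Gnas-211, whose first base lies 45769 bases upstream of that of Gnas-208, took 54.5 and 56.4% of UMIs in the class (1889 and 3058 UMIs of the gene) against 4.81 and 3.09% in beta cells, a difference of 51.5 ± 2.59 points (adjusted p = 2.5e-24). Its 759 coding bases lie in exon 2 (chromosome 2, 174284604 to 174285477), outside the sequence of Gnas-208, which stood at 8.79 and 6.74% in the class. In alpha cells Gnas-211 took 12.4 and 18.6%, and in PP cells 10.4 and 18.01%. The antisense gene Nespas overlaps exons 1 and 2 of Gnas-211, and strand use is not given in the sources used here.

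**Figure D2:**
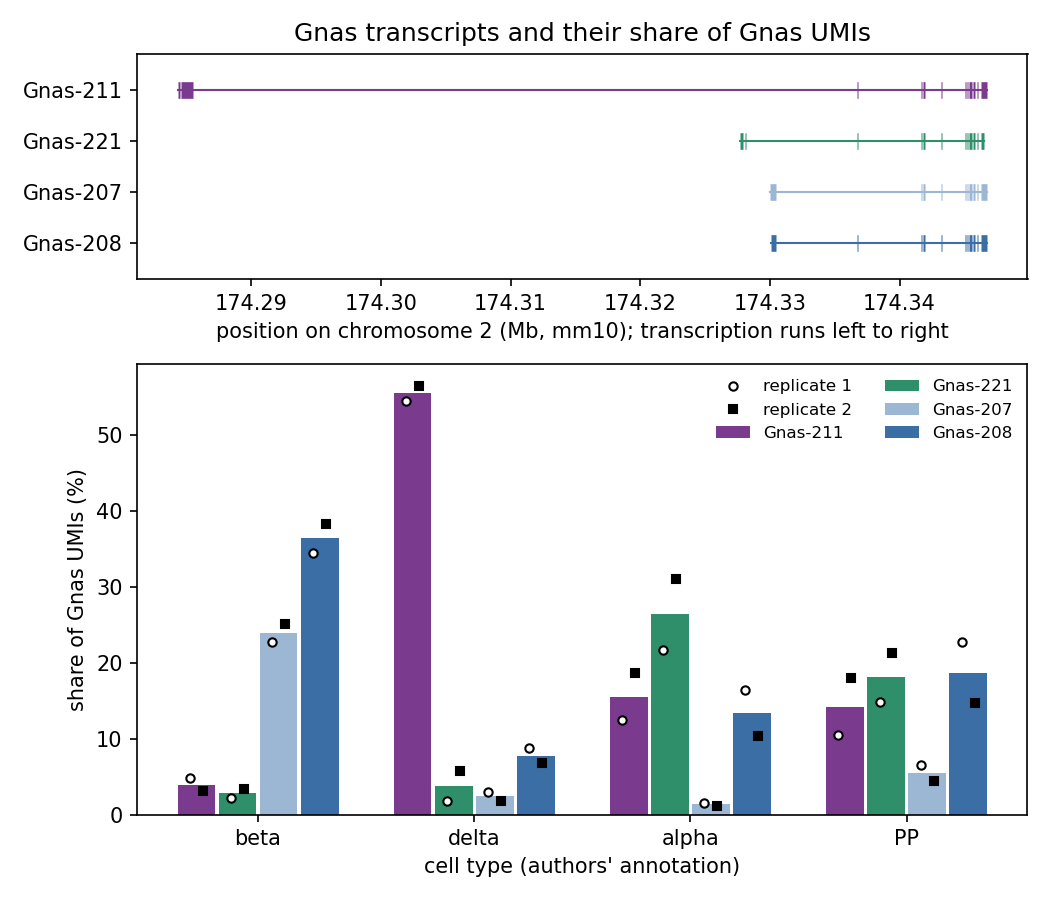
Annotated exons of 4 Gnas transcripts along chromosome 2 (upper panel) and the share of Gnas UMIs (%) taken by each transcript per cell type and replicate (lower panel). Gnas-211 takes 54.5 and 56.4% in the delta class, and Gnas-221 takes 21.7 and 31.0% in alpha cells.

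Coro2b-203, from an actin-binding coronin gene, took 25.3 and 48.3% in the delta class against 5.24 and 3.21% in beta cells (32.6 ± 17.7 points, adjusted p = 1.3e-07), Eml2-202, from a microtubule-associated protein gene, was 34.8 ± 6.74 points higher (adjusted p = 0.0016), and Rasgrf1-202, from an exchange factor for Ras, 18.7 ± 0.467 points higher (adjusted p = 0.00059). Sumo3-202 took 13.01 and 9.20% against 33.5 and 27.9% (own adjusted p = 0.023). Cltb-201, a clathrin light chain transcript with 54 more coding bases, took 6.37 and 8.15% against 0.781 and 0.635% (adjusted p = 8.3e-10). Further calls were Tmem219 (adjusted p = 0.0068), Arid4a (0.020) and Atf4 (0.020). These 3 calls and those at Eml2, Rasgrf1 and Sumo3 ended without the library block. Other calls were Klc1, a kinesin light chain (38.1 ± 10.95 points, adjusted p = 0.0056), the tau gene Mapt (0.00014), Clta (gene 6.4e-20, with Clta-203 up by 6.83 ± 1.08 points at an own adjusted p of 0.032), Cdc42, a small GTPase (13.4 ± 3.03 points, 3.2e-05), Tecr (0.0032), Bscl2 (0.0016) and Exoc7 (0.012). These 7 calls ended when only clusters led by their own markers were kept, and Klc1 then stood at -4.19 points.

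PP cells differed from beta cells in the mix of transcripts in 35 of 5064 genes (edgeR diffSpliceDGE). Gnas-221 was 15.3 ± 3.76 points higher than in beta cells (adjusted p = 2.6e-11) and Sumo3-202 25.2 ± 2.66 points lower (own adjusted p = 0.00038). Tsc22d1-213, a transcript of a leucine-zipper gene annotated for nonsense-mediated decay, took 1.33 and 0.595% against 13.4 and 20.9% in beta cells (own adjusted p = 2.8e-07), on 2 and 1 UMIs in PP cells. Pax6-207, from a homeobox gene of islet development, took 27.3 and 27.8% against 10.0 and 6.17%, with only 88 and 54 UMIs of the gene in PP cells (19.4 ± 3.08 points, adjusted p = 0.019). Dusp1 (adjusted p = 4.8e-07), Eif4a2 (0.0011), Tmem176a (0.018) and Arpc5 (0.018) also passed, and shares at Fosb, Clk1 and Rpl22l1 were unequal between libraries, as in Clk1-210 at 6.15 and 42.0% in PP cells. Without the library block all of these calls ended except Gnas, Sumo3 and Tsc22d1.

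Endothelial and stellate cells together differed from the 4 endocrine types in the mix of transcripts in 66 of 6368 genes (edgeR diffSpliceDGE). Of the cells named endothelial, 12 in replicate 1 and 16 in replicate 2 (8.51 and 61.5%) lay in a cluster with the duct markers Spp1 and Krt19. With only own-marker clusters, which left stellate cells alone as the non-endocrine side, 25 of the 66 genes were called. In this and the next paragraph a share is the unweighted mean of the shares of the types on a side, while UMIs are summed over them. Shares for endothelial and stellate cells apart are not given. Rps24-205, from a ribosomal protein gene, which holds an 18-base exon (chromosome 14, 24494052 to 24494069), took 32.6 and 26.5% in non-endocrine cells (466 and 933 UMIs of the gene) against 3.40 and 3.18% in endocrine cells (15374 and 34367 UMIs), 26.3 ± 4.16 points more (adjusted p = 4.0e-52). Of the summed non-endocrine UMIs, it held 149 of 466 and 164 of 933, so mean and pooled shares differ in replicate 2. At the tropomyosin gene Tpm1, Tpm1-215 took 30.9 and 35.5% against 0.605 and 0.212% (32.8 ± 3.52 points, adjusted p = 2.4e-14), and it carries a 76-base coding exon (chromosome 9, 67031951 to 67032026) where Tpm1-212 carries another (67032466 to 67032541). Tpm1-215 held 60 of 115 and 49 of 127 summed non-endocrine UMIs. Myl6-201, a myosin light chain transcript that lacks a 45-base exon (chromosome 10, 128491720 to 128491764), took 62.3 and 70.3% against 29.6 and 31.5% (35.7 ± 4.26 points, adjusted p = 6.6e-09). App-201, from the amyloid precursor gene, took 10.6 and 3.61% against 32.7 and 33.5% (-26.0 ± 5.53 points, own adjusted p = 0.0040), while App-204, with a 168-base coding exon (chromosome 16, 85043576 to 85043743), did not pass its own test (adjusted p = 0.0687).

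Some transcripts with short exons took less in non-endocrine cells: Cd47-205, from a surface protein gene, with a 33-base coding exon (chromosome 16, 49908703 to 49908735), took 1.09 and 0.667% against 20.4 and 18.5% in endocrine cells (adjusted p = 1.6e-15), and Psap-205, from the prosaposin gene, with a 9-base coding exon (chromosome 10, 60297537 to 60297545), took 1.59 and 5.23% against 29.9 and 31.1% (adjusted p = 7.0e-10). Gsn-205, a gelsolin transcript, took 17.5 and 43.6% against 68.8 and 80.3% (own adjusted p = 3.9e-11), while Gsn-201, which has another first exon (chromosome 2, 35282380 to 35282601), did not pass its own test (adjusted p = 0.169). Gsn-205 held 12 of 645 and 27 of 97 summed non-endocrine UMIs. Tsc22d3-201, from a glucocorticoid-induced gene, took 91.6 and 80.3% against 35.1 and 40.7% (own adjusted p = 0.011, gene adjusted p = 7.2e-08). The remaining named genes were Ap2m1 (Ap2m1-202 at 61.9 and 22.5% against 7.11 and 6.16%, adjusted p = 2.3e-09), Sptbn1 (2.4e-07), Aldoa (0.00064), S100a16 (0.0019), Prkar1a (0.0097), Hspa5 (0.033), Dusp1 (5.6e-06) and Fosb (0.0024). With UMIs thinned to equal totals, which left 1157 genes to test, the calls at App, Gsn, Tsc22d3, S100a16, Aldoa, Prkar1a, Sptbn1, Hspa5, Dusp1 and Fosb ended, and that at Myl6 ended without the library block. The calls at App, Tsc22d3, S100a16, Aldoa, Prkar1a, Sptbn1, Hspa5, Dusp1 and Fosb also ended with only own-marker clusters.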

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

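The tests for free RNA, for droplets that join an islet cell to a nerve cell, for Gnas-211 in the delta-marker cluster and for Gnas-211 with thinned UMIs were chosen only after the result was seen. The design names no biological group that differs between cell types, so no biological explanation was tested.

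Barcodes left out of the authors' cell table carried hormone transcripts: Ins1, Ins2, Gcg, Sst, Ppy and Iapp took 12.5% of the UMIs of 1581 such barcodes in replicate 1 and 2.77% of those of 1031 barcodes in replicate 2, against 17.8 and 14.2% in kept cells. These barcodes had medians of 651 and 3178 UMIs, and 3.66 and 7.47% of their UMIs were mitochondrial, against 1.07 and 2.00% in kept cells. They are data that no comparison used and have no control to set beside them.

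Clusters 8 and 12 of the delta class held Sst together with a second hormone, Ins2 with Iapp or Gcg. The second hormone was at least 6.17 times its level in the delta-marker cluster of the same library. The clusters were picked for holding that hormone, so this ratio cannot decide on free RNA. Droplets with 2 cells remain a candidate explanation: over genes that set the partner cluster apart, the median level was 0.391 to 0.639 of the partner's, and over delta genes 0.407 to 0.486 of the delta-marker cluster's. Of these cells, 36.6 to 55.2% were among the highest doublet scores. A single cell that runs both programmes would give the same values, so it stays open.

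The largest rises in the delta class lay mostly in cluster 16, of 7 and 7 cells. Over the 12 genes, a median of 97.7% of the class's UMIs in replicate 1 and 99.1% in replicate 2 came from that cluster, which may make a few nerve-like cells the source of 8 of the 12 rises, with Ptn, Gap43, Cd24a and Ldha (3.68 with only own-marker clusters) as exceptions. Over all rises of the class the median was 3.12 and 6.12%, so these cells are not the source of most of the 1165. Droplets that join an islet cell to a nerve cell are argued against, since Gcg, Sst, Ppy and Iapp together reached at most 1.14% of their share in the delta-marker cluster. The cells had 5.90 and 4.59 times the median UMIs of their library and 0% were among the highest doublet scores.

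Gnas-211 took 54.5 and 56.4% of Gnas UMIs in the delta class against 4.81 and 3.09% in beta cells. A few cells of another type are argued against, since the share was at least 62.3% in the delta-marker cluster alone. Longer molecules in delta cells are argued against too, since over 2695 genes the most upstream transcript differed by a median of -0.923 points in replicate 1 and 1.35 points in replicate 2. With UMIs thinned to equal totals the difference was 51.2 points. Random thinning leaves the expected share of a transcript unchanged, so this cannot decide whether unequal depth is a source. Reads from the antisense gene Nespas stay open, because strand use is not given, and a use of the upstream promoter in delta cells is a hypothesis from the same data.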

How the results depend on the processing

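The alternatives with the authors' clusters from transcripts, with own-marker clusters only and without the highest doublet scores were chosen only after the data were seen. Under every alternative run except those 2 sets of clusters, all 207 named gene changes kept their direction (206 of the 206 tested in the fit of 2 types), and 196 stayed past the threshold with DESeq2, 194 without TMM scaling, 202 without a filter and 202 with thinned UMIs. Without the library block 152 did. The kept direction is a weak check, since these alternatives reuse the same libraries and the genes were named for passing in the main fit. Leaving out either replicate is no check on named genes, as the naming rule asked for the same direction in each library. A filter on UMIs and mitochondrial share removed no cell and gave no new value. Of 57 isoform calls, 31 ended without the library block, 23 with thinned UMIs, 8 with a filter of 2 UMIs, 2 of 53 with a filter of 30 UMIs and 10%, and 1 with limma. Of 56 tested, 17 ended and 1 reversed with own-marker clusters, and 10 ended and 4 reversed with the authors' clusters from transcripts. Depth limits the small types most: the non-endocrine isoform test fell from 6368 to 1157 genes with thinned UMIs, and its calls from 66 to 14.

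Gene counts moved over 1.5 times as follows. Without TMM scaling 4043 genes differed in alpha cells (main 2525). Without the library block 1281 did in alpha cells, 862 in the delta class (main 1829) and 1149 in PP cells (main 2297). For the delta class DESeq2 gave 1195, a fit of 2 types 3258 and own-marker clusters 2907, of which 1500 were main calls. Thinned UMIs gave 1521 in PP cells, with fewer genes tested. Isoform counts by limma were 521 in alpha, 284 in delta, 353 in PP and 356 in non-endocrine cells (main 55, 49, 35 and 66), and without the library block 13, 20, 9 and 38. For PP cells a filter of 2 UMIs gave 23 genes, thinned UMIs 17 and own-marker clusters 57. Own-marker clusters gave 36 non-endocrine genes, with stellate cells alone. Apart from the smaller tests, the cause was not tested.

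Under the authors' clusters from transcripts, which name 7 and 6 of the nerve-like cells beta, fold changes reversed. Of the 1829 main calls in the delta class, 191 took the opposite sign. In the same direction 1189 (65.0%) were called again. Against beta, Rtn1 went to -1.38 in alpha, -2.17 in delta and -1.28 in PP cells. In the delta class Lgals1 went to -5.64, Prph to -6.96, Fxyd7 to -6.30, Sncg to -6.97, Vip to -6.36, Gng3 to -5.39, Stmn2 to -5.82, Anxa2 to -6.01, Ldha to -3.09, Snrpn to -0.24 and Snhg11 to -0.49. Differences in isoform share there went to -38.5 points for Klc1 (main 38.1), 3.94 for Mapt-204 (main -25.3), -5.26 for Tecr (main 19.6) and -5.64 for Cdc42 (main 13.4). With own-marker clusters Sncg went to -0.54 and Klc1 to -4.19 points, neither past the threshold. Nor were the reversed values of Snrpn, Snhg11, Tecr and Cdc42 past it. Both alternatives take those cells out of the delta class by construction, and no other cause was tested.

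With transcripts counted from 5 UMIs, 33709.5 were detected per library on average. Genes with such a transcript had 2.10 on average, and 50.0% of these genes had at least 2. Stellate cells were 2.48% without Scrublet doublets and 2.41% without the highest scores (main 2.46%). Cells named by hormone gave 27.2% alpha and 7.92% PP among endocrine cells, as means over the libraries. By the authors' types these shares were 21.4 and 23.1% alpha and 6.30 and 3.97% PP in replicates 1 and 2. Beta cells were named by Ins1 and Ins2, targets of the removal panel. Of the 470 and 118 cells named otherwise, 298 and 73 were of the delta class, and the cause was not tested.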

Other observations

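The values from own-marker clusters come from an alternative chosen only after the data were seen, as was the choice of the genes and clusters named here, and no test of a hypothesis is added to those already given.

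With the other clusters of the class left out, the delta cells of the cluster led by delta markers had 1500 genes higher and 1407 lower than beta cells of own-marker clusters (edgeR). Genes high here can be high in other endocrine types too, as Ache was in PP cells. Cd24a, a surface glycoprotein gene, stood at 515 ± 28.0 CPM against 2.03 ± 0.166 (SD over 2 libraries), with a log2 fold change of 8.09 ± 0.28 (SE from the fit). Arg1, the arginase of the urea cycle, stood at 649 ± 0.379 against 4.07 ± 2.34, and Ly6h, which encodes a neural surface protein, at 493 ± 63.1 against 2.96 ± 1.49. Gap43 stood at 360 ± 90.0 CPM against 1.47 ± 0.576, Hspb1, a small heat shock protein gene, rose by 6.85 ± 0.29 and Ache by 6.74 ± 0.34. Ppp1r17, an inhibitor of protein phosphatases, stood at 116 ± 6.92 CPM, with 2 UMIs in beta cells of replicate 1 and 0 in replicate 2. The largest falls were Nupr1 (3.77 ± 0.196 against 200 ± 35.4 CPM, -5.55), Cox6a2 (-5.38), Tmigd3 (-5.29), Gstm2 (-4.51) and Trpm5 (-4.50).

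By list, 16 of 24 ER folding genes were lower in these delta cells and 0 higher (median log2 fold change -0.72), and 15 of 18 immediate early genes were higher and 0 lower (median 1.48). Of 18 receptor genes 3 were higher and 11 lower, and of 18 ion channel genes 8 were higher and 3 lower. Sncg, called higher in the whole class, stood at a log2 fold change of -0.54 here and was not called (edgeR adjusted p = 0.816).

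A cluster of 12 and 16 cells that the authors name endothelial carried Spp1 at 19202 and 13409 CPM and Krt19 at 829 and 1050 CPM, both markers of ducts. Cd79a, a component of the B-cell receptor, stood at 169 and 86.2 CPM in beta cells against 2.62 and 9.19 CPM in alpha cells. Ghrl, the ghrelin gene, reached 3839 CPM in the cluster with Sst and Gcg in replicate 1 and stood at 0 CPM there in replicate 2. The number of barcodes shared by the cells of both libraries was 5.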
